A study of Mus musculus with 3 samples.

How the data were processed

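The data were 1 group of 3 libraries of total RNA, depleted of ribosomal RNA, from the cytosolic fraction of C57BL/6J bone marrow-derived macrophages stimulated with lipid A, each made from 1 µg of RNA per the labels. Per the text descriptions deposited beside the files, the authors aligned reads to mm10 with the GENCODE M21 annotation and deposited, for each library, gene and transcript values derived from transcriptome alignments (called the first quantification) and transcript values derived straight from 8, 10 and 10 FASTQ files for replicates 1, 2 and 3 (the second quantification). Per the file headers, the first holds expected counts, TPM, FPKM and effective lengths, a column layout that matches RSEM, and the second holds estimated counts and TPM, a layout that matches kallisto; names and versions of these tools are not given in the sources used here. The deposited TPM values add up over everything quantified in a library, spike-in sequences, phiX174 and small RNAs included. The deposited FPKM values were used only in an alternative. Whether counting used the strand is not given in the sources used here, so values of overlapping genes on opposite strands are uncertain.

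Each gene table held 81881 entries, of which 55536 were annotated genes and all of these matched GENCODE M21 identifiers. The rest were 26248 numbered entries, 96 ERCC spike-ins and 1 phiX174 entry, which were left out of the comparisons. Values of 115 symbols carried by more than 1 identifier were summed, giving 55418 symbols. The first quantification held 141862 annotated transcripts and the second 141767. Counts on annotated genes were 33671556, 47764593 and 59332546 in replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.0891, 0.0628 and 0.0506 CPM, for counting error only, since reads without molecular identifiers are not independent molecules.

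Before the data were examined, 30 gene lists, 19 contrasts between them, the tests, the alternatives and the rule for named genes were fixed. Of the listed symbols, 2 were not found (Snord3a and Gnb2l1, the latter present as Rack1 and not added). In each library the median log2(TPM + 0.1) of a list was set against the median of protein-coding genes with a mean of at least 1 TPM. The 49 list levels and contrasts were tested with limma 3.58.1 (one-sample moderated test, Benjamini-Hochberg adjustment, threshold 0.05). The unit of these tests is the library, so a small p means that a difference repeated in the 3 libraries. It does not measure the spread between the genes of a list. Levels and contrasts share the reference and list members, so the variance pooled over them comes from values that depend on each other. An exact sign-flip test cannot go below p = 0.25 with 3 libraries (two-sided); it gave that value for every list and contrast except the late genes (0.5) and the secretory minus housekeeping contrast (1). The level of a list was also placed among 10000 random protein-coding lists of its size, as a description. The reference leaves out protein-coding genes under 1 TPM, while lists and random lists keep them. Single genes with a mean of at least 0.1 TPM were tested in the same way, and a call needed an absolute log2 difference of at least 1; counts were also taken with p adjusted over the list alone. The replicate labels number 1 group, so no contrast between samples was possible.

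Variation between the libraries was measured on rounded expected counts of genes with at least 10 counts in every library, scaled by TMM (edgeR 4.0.16, R 4.3.3), as log2 CPM with a prior count of 2. The median SD of each list with at least 5 members was compared with 10000 random lists matched in 20 bins of mean expression (two-sided permutation p, smallest possible 0.0002). Each gene was tested for fit to the trended dispersion with the edgeR goodness-of-fit function. Every pair of libraries differed by far more than counting error, with chi-square per degree of freedom of 102, 162 and 46.2, so none was a copy of another. Retained-intron shares were taken per gene from the transcript biotypes, for genes with a total of at least 1 TPM and both kinds of transcript, and the differences of list medians from the housekeeping genes were tested with limma. The quantifications were compared per gene by limma on the median-centred log2 ratio of TPM, for genes with a mean of at least 1 TPM in either. DESeq2 1.42.0 size factors served as an alternative scaling. Near-identical copies were searched by aligning the transcripts of named genes to all annotated transcripts.

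The steps were tested on simulated data drawn for 12330 genes. The goodness-of-fit step recovered 78.0% of 200 genes raised 2-fold in 1 library, with 5 false calls, and 99.5% of those raised 4-fold, with 1. The one-sample step recovered 100% of 200 genes shifted by 1.5 log2 units with 0 false calls. The spread simulated for this step was small beside the shift and the minimum difference of 1, so this outcome was nearly fixed in advance. It gives no error rate for genes that vary more between the libraries. The matched-list step called 100% of 100 lists whose SD was doubled, and 6 of the same number of unchanged lists at an unadjusted p under 0.05. The simulated genes varied independently of each other, whereas members of a real list can move together, so this error rate need not hold for the real lists. The goodness-of-fit simulation used a single coefficient of variation, lower than the common one of 14.9% estimated from the libraries.

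The text names, by the fixed rule, the 3 most abundant members of each list, the 2 lowest of the immediate early, cytokine, feedback, interferon-stimulated, late and TLR4 lists, 16 response and control genes chosen in advance, the 10 most abundant nuclear protein-coding genes, the 10 most variable genes and the 6 genes that differed most between the quantifications (each with a mean of at least 10 TPM in the first), and 13 genes for isoforms, 135 in all; any other gene is said to be named after its values were seen. The result of a listed gene that is withheld for evaluation is not reported here. The alternatives were other pseudocounts (1 and 0.01), filters, list means, FPKM, the second quantification, other references, DESeq2 size factors, common or tagwise dispersion, no minimum difference, and leaving out each replicate in turn. They were all chosen before the data were examined. Genes are placed in mm10 coordinates, counted from 1.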

Results

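RNA depleted of ribosomal RNA was sequenced from the cytosol of bone marrow-derived macrophages of the mouse strain C57BL/6J. The cells had been given lipid A, the part of bacterial lipopolysaccharide that Toll-like receptor 4 (TLR4) recognises, at 100 ng/ml for 90 min. The samples form 1 group of 3 libraries, numbered as biological replicates 1 to 3 in the labels, which give them the same donor identifier and do not record the sex. The total expected counts were 33821479, 47843161 and 59390843 in replicates 1, 2 and 3, and 12492, 13287 and 14260 genes had at least 10 of them. Untreated cells and nuclear RNA were not analysed here, so neither the induction of a gene nor its split between nucleus and cytosol was measured. Levels were therefore compared between genes within each library. The reference was the median of 8747 protein-coding genes with a mean TPM (a share of all transcripts, corrected for length) of at least 1, which was 7.38, 6.08 and 6.21 TPM in replicates 1, 2 and 3. Of 13327 genes tested, 2726 lay above the reference by a log2 difference of at least 1, 6742 lay below it by as much and 3859 did neither (limma, Benjamini-Hochberg threshold 0.05). A list below the reference need not be low among all protein-coding genes. Among 10000 random protein-coding lists of equal size, the late, stress, histone and cell cycle lists stood at percentiles 99.49, 95.1, 99.99 and 89.4. The nuclear-retained, alternative activation, dendritic cell and neutrophil lists stood at 64.33, 62.95, 57.88 and 52.88. The other lists below it stood at 0 (Y-linked genes) to 38.83 (endothelial markers). Every list level and contrast past the threshold had the same sign in 3 of 3 libraries, as had the genes named with a p past it. Every error given is an SD over the 3 libraries. Neither these errors nor the limma p-values of lists and contrasts measure the spread between the genes of a list. In all lists the counts of called genes were the same when p was adjusted over the list alone.

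Small noncoding RNAs made up most of the TPM in the first of the deposited quantifications, the one used throughout. The 7SL RNA of the signal recognition particle, which targets secretory proteins to the endoplasmic reticulum, held 61.9% ± 2.31 of the TPM and 10.7% ± 1.59 of the expected counts (SD, n = 3). The 7SK RNA, a regulator of transcription elongation, held 6.45% ± 2.75 of the TPM, and the RNA components of RNase P and RNase MRP together 5.95% ± 1.34. Nuclear-encoded protein-coding genes held 23.1% ± 2.84 of the TPM but 84.4% ± 3.05 of the expected counts, since TPM divides by length and the small RNAs are short. Mitochondrially encoded mRNAs, without their annotated copies on chromosome 1, held 0.581% ± 0.283 of the TPM. Ribosomal RNA genes held 0.218% in replicate 1 against 0.00279% and 0.00882% in replicates 2 and 3. The second quantification divided the TPM differently, with 37.4% ± 9.57 on pseudogenes, 28.4% ± 2.42 on other classes, 20.3% ± 4.96 on 7SL, 2.08% ± 0.655 on 7SK, 1.89% ± 0.258 on RNase P and MRP and 9.50% ± 2.93 on nuclear-encoded protein-coding genes, so these shares depend on the quantification.

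Cytokine and chemokine mRNAs were among the most abundant in the cytosol. The median of the 18 listed genes lay 5.20 ± 0.17 log2 units above the reference (SD, n = 3), 36.7-fold, in 3 of 3 libraries (limma, Benjamini-Hochberg adjusted p = 1.59e-06). The chemokines Ccl4 and Ccl3, which attract monocytes and T cells, averaged 1372 ± 534 TPM and 1108 ± 383 TPM. Il1b, which encodes the pyrogenic cytokine interleukin-1 beta (ENSMUSG00000027398.13, chromosome 2, 129364570 to 129371139, mm10), averaged 970.0 ± 140.3 TPM. Tnf, which encodes tumour necrosis factor (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007), averaged 764 ± 162 TPM, and lay 6.83 ± 0.32 log2 units above the reference (limma, Benjamini-Hochberg adjusted p = 3.46e-05). Of the list, 15 genes lay above the reference over all genes, and 15 when adjusted over the list alone. The other 3 were Il23a at 8.67 ± 3.21 TPM, named after its values were seen, the neutrophil chemoattractant Cxcl3 at 7.52 ± 2.48 TPM, and Lif, a cytokine of the interleukin-6 family, at 1.91, 3.33 and 6.48 TPM in replicates 1, 2 and 3. Without replicate 3, Lif lay below the reference (-1.37 log2 units, against -0.89 with all libraries). Ptgs2, which encodes the inducible prostaglandin synthase, averaged 57.3 ± 1.90 TPM, and Il1rn, which encodes the interleukin-1 receptor antagonist, 141 ± 28.0 TPM. The list lay above the immediate early genes by 2.96 ± 0.16 log2 units (limma, Benjamini-Hochberg adjusted p = 8.87e-06), above the feedback regulators by 2.15 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 2.65e-05), and above the interferon-stimulated genes by 2.39 ± 0.41 (limma, Benjamini-Hochberg adjusted p = 0.000161).

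**Figure D1:**
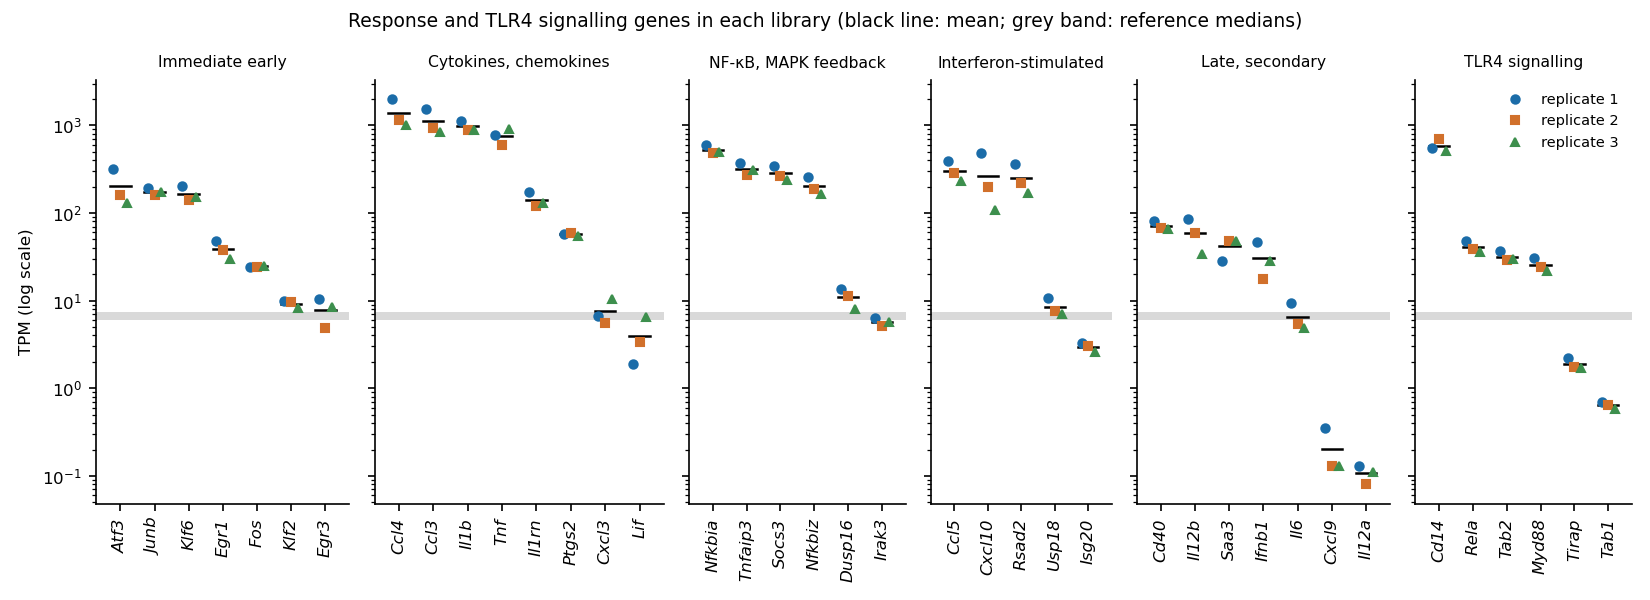
TPM (log scale) of named response and TLR4 signalling genes in replicates 1, 2 and 3, with the mean as a black line and the range of the reference medians, 6.08 to 7.38 TPM, as a grey band. Tnf sits between 597 and 919.6 TPM, while Cxcl10 spreads from 109 to 482 TPM.

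Feedback regulators and pathway members of nuclear factor kappa B (NF-kB) and of mitogen-activated protein kinases (MAPK) also lay above the reference, by 3.05 ± 0.04 log2 units (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 4.19e-06). Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647), which encodes the inhibitor that holds NF-kB in the cytosol, averaged 526 ± 58.2 TPM and varied little between the libraries, with 592, 483 and 502 TPM. Tnfaip3, which encodes the ubiquitin-editing enzyme A20, averaged 318 ± 47.4 TPM, and Socs3, an inhibitor of cytokine receptor signalling, 282 ± 52.9 TPM. Of 25 regulators, 23 lay above the reference over all genes and 23 when adjusted over the list alone. The other two were the MAPK phosphatase Dusp16 at 10.9 ± 2.72 TPM and the receptor kinase homologue Irak3 at 5.71 ± 0.646 TPM. The immediate early genes, transcription factors and regulators that are transcribed within minutes of a stimulus, lay 2.24 ± 0.01 log2 units above the reference (limma, Benjamini-Hochberg adjusted p = 1.07e-05), with 14 of 17 genes above it over all genes and 14 when adjusted over the list alone. Atf3 gave 313, 161 and 129.6 TPM in replicates 1, 2 and 3, Junb averaged 175 ± 18.3 TPM and Klf6 165 ± 32.7 TPM. Egr1 averaged 38.4 ± 8.79 TPM and Fos 24.6 ± 0.223 TPM. Egr3, Klf2 and Myc, the last named after its values were seen, averaged 7.88, 9.22 and 9.69 TPM and were not called. In the second quantification Egr3 and Klf2 lay just below the reference (-0.09 and -0.05 log2 units, against 0.20 and 0.49).

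Interferon-stimulated genes lay 2.81 ± 0.25 log2 units above the reference (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 2.50e-05), with 22 of 26 genes above it and 1 below over all genes, and 22 and 1 when adjusted over the list alone. The chemokine Ccl5 averaged 304 ± 82.9 TPM and Rsad2, which encodes the antiviral enzyme viperin, 249 ± 99.4 TPM. Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889), a chemokine for T cells, gave 482, 198 and 109 TPM in replicates 1, 2 and 3. The exonuclease gene Isg20 lay below the reference at 2.95 ± 0.351 TPM, a call lost with a pseudocount of 1 (-0.93 log2 units, against -1.13). Usp18, which restrains interferon signalling, was not called at 8.48 ± 2.07 TPM, nor were Mx1 and Mx2 at 12.8 and 10.2 TPM, named after their values were seen. Mx2 is annotated as a polymorphic pseudogene. Ifnb1, encoding interferon beta, an inducer of these genes, averaged 30.8 ± 14.6 TPM. Replicate 1 was the highest of the libraries for 23 of the 26 genes, by a median of 1.24-fold over the mean of the other two.

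Genes listed as late and secondary response genes, many of which need new protein or longer stimulation, lay near the reference at -0.12 ± 0.28 log2 units (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.452), and the group was split. Cd40, a co-stimulatory receptor, averaged 71.1 ± 8.23 TPM, Il12b, encoding the p40 subunit shared by interleukins 12 and 23, 59.6 ± 25.4 TPM, and the acute-phase gene Saa3 41.7 ± 11.3 TPM. These genes and Ifnb1 lay above the reference, 4 of 14 over all genes and 4 when adjusted over the list alone. Cxcl9 at 0.203 ± 0.127 TPM and Il12a at 0.107 ± 0.0252 TPM lay below it with Nos2, Marco and Csf3 at 0.960, 1.19 and 0.810 TPM, which were named after their values were seen. Il6 averaged 6.56 ± 2.50 TPM, near the reference at -0.06 ± 0.36 log2 units (limma, Benjamini-Hochberg adjusted p = 0.754), and with Lcn2, Il27, Edn1 and Ccl8 made up the 5 without a call, all but Il6 named after their values were seen. The list lay 5.32 ± 0.38 log2 units below the cytokines and chemokines (limma, Benjamini-Hochberg adjusted p = 6.67e-06) and 2.92 ± 0.14 below the interferon-stimulated genes (limma, Benjamini-Hochberg adjusted p = 7.80e-06). With FPKM the list lay at 0.10 log2 units, with the list mean at -0.43 and in the second quantification at -0.61, the last 2 of which passed the threshold.

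**Figure D2:**
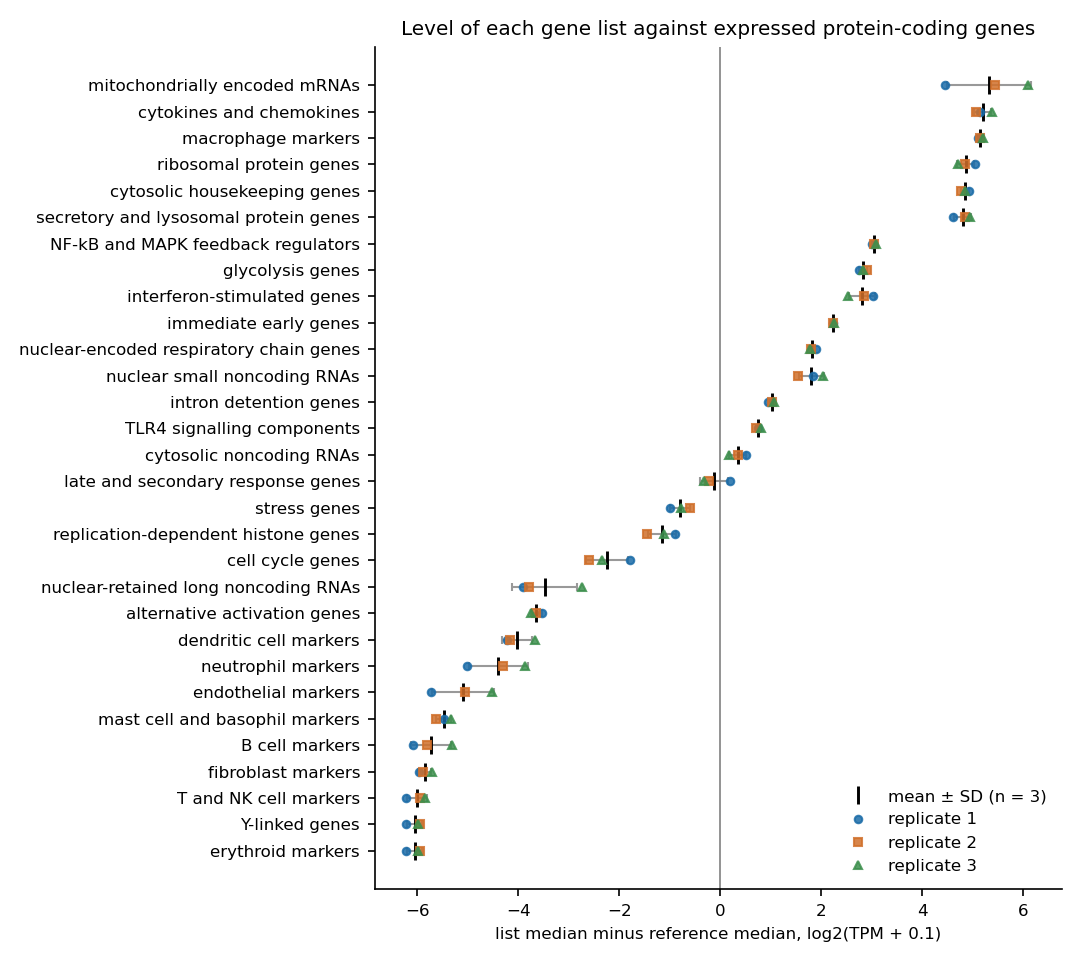
Median log2(TPM + 0.1) of each of the 30 gene lists minus the reference median of the same library, with replicates 1, 2 and 3 as points and the mean ± SD (n = 3) as a bar with whiskers. The lists span -6.05 (erythroid markers and Y-linked genes) to 5.33 (mitochondrially encoded mRNAs), and the levels under about -5 are set by the pseudocount.

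Components of the TLR4 pathway covered a wide range, with a list median 0.76 ± 0.05 log2 units above the reference (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00076). The co-receptor gene Cd14 averaged 585 ± 98.4 TPM, the NF-kB subunit gene Rela 41.0 ± 6.41 TPM, the adaptor gene Tab2 31.8 ± 4.09 TPM and the adaptor gene Myd88 25.6 ± 4.69 TPM. Tlr4 averaged 15.2 ± 3.85 TPM. Of 22 components, 10 lay above and 3 below the reference over all genes, and 10 and 3 when adjusted over the list alone. Those below were the adaptor genes Tirap at 1.89 ± 0.284 TPM, Tab1 at 0.640 ± 0.0557 TPM and Tab3 at 2.32 ± 0.256 TPM, the last and Tlr4 being named after their values were seen. The list median lay at -0.27 log2 units against a reference of genes with at least 5 TPM, and at 0.26 in the second quantification, where it no longer passed the threshold. Of the 9 genes of alternative activation, a state driven by interleukin 4, the mannose receptor gene Mrc1 lay above the reference at 110.4 ± 6.15 TPM, whereas Mgl2, Ccl24 and Cd163, named after their values were seen, lay below it at 0.367, 1.72 and 0.427 TPM. The list lay -3.64 ± 0.11 log2 units from the reference (limma, Benjamini-Hochberg adjusted p = 3.21e-06), or -1.39 over the members with a mean of at least 10 counts. Among random protein-coding lists of its size it stood at percentile 62.95. Arg1 and Retnla, also named afterwards, were at 0 TPM in 3 of 3 libraries, the list median was 0.427 TPM, and 1 and 3 genes were called when adjusted over the list alone. The list lay 8.79 ± 0.16 log2 units below the macrophage markers (limma, Benjamini-Hochberg adjusted p = 4.50e-07). The stress genes lay -0.79 ± 0.20 log2 units from the reference (limma, Benjamini-Hochberg adjusted p = 0.00199), with 5 of 11 genes above and 3 below it over all genes and 5 and 3 when adjusted over the list alone. Gadd45b, a growth arrest gene that is also a target of NF-kB, averaged 167 ± 23.4 TPM and Hmox1, encoding heme oxygenase 1, 69.4 ± 10.6 TPM, as against 3.69 TPM for the heat shock gene Hspa1a, named after its values were seen. The stress list mean, unlike its median, lay above the reference (0.33 log2 units).

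Macrophage markers lay 5.15 ± 0.05 log2 units above the reference (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 9.39e-07), with 15 of 16 genes above it over all genes and 15 when adjusted over the list alone. The lysozyme gene Lyz2 averaged 4347 ± 1009 TPM, the lipid carrier gene Apoe 1685 ± 239 TPM and the galectin gene Lgals3 1242 ± 149.8 TPM. Markers of other marrow and blood cells were mostly near 0, with list medians of 0.228 TPM for neutrophils, 0.00667 for T and NK cells, 0.0200 for B cells, 0.335 for dendritic cells, 0.00333 for erythroid cells, 0.0217 for fibroblasts, 0.0550 for mast cells and basophils and 0.132 for endothelium. The differences between the macrophage markers and these lists passed the threshold (limma, Benjamini-Hochberg adjusted p = 2.35e-06 for neutrophil markers, the largest p of these lists), but their size is set by the pseudocount of 0.1 TPM. A few markers stood higher. The neutrophil calprotectin genes S100a9 and S100a8 averaged 19.3 ± 5.51 TPM and 12.2 ± 3.86 TPM, Cd4 18.5 ± 2.89 TPM, the endothelial gene Vwf 8.32 ± 1.48 TPM, the chemokine gene Ccl22 5.22 ± 0.733 TPM and the immunoglobulin gene Ighm 3.59 ± 1.87 TPM. Of these, S100a9 and Cd4 lay above the reference over all genes and when adjusted over the list alone, but lost the call in the second quantification (0.94 and 0.99 log2 units). Across the neutrophil, T and NK, B, dendritic, erythroid, mast and endothelial lists, 5, 1, 2, 5, 1, 3 and 2 genes lay below it on either adjustment, and no fibroblast gene reached the 0.1 TPM needed for a test. The granule gene Ngp, below the reference at 2.40, 2.54 and 4.14 TPM, lost its call without replicate 1 (-0.90 log2 units) and without replicate 2 (-1.08), against -1.13 with all libraries. Without replicate 1, Ighm lay below the reference (-1.26, against -0.96), and without replicate 2, S100a8 lay above it (1.07, against 0.83). All 4 Y-linked genes were at 0 TPM in 3 of 3 libraries, and Xist, the RNA that silences an X chromosome in females, gave 2.16, 2.97 and 10.3 TPM. Counts of 0 allow up to 0.0891, 0.0628 and 0.0506 CPM in replicates 1, 2 and 3, for counting error only.

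The median of the listed housekeeping mRNAs, which are translated on free ribosomes, was far above that of the listed long noncoding RNAs retained in the nucleus. Housekeeping genes are abundant mRNAs, and no nuclear RNA was measured, so this contrast does not show where an RNA resides. The nuclear-retained list stood at percentile 64.33 among random protein-coding lists of its size. The housekeeping genes lay 4.85 ± 0.09 log2 units above the reference (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 1.20e-06), with 19 of 19 genes above it, as when adjusted over the list alone. Actb, encoding beta-actin, averaged 1793 ± 259 TPM and Tmsb4x, encoding an actin-binding peptide, 1889 ± 259 TPM. The nuclear-retained long noncoding RNAs had a median of 0.533 TPM, -3.47 ± 0.64 log2 units from the reference (limma, Benjamini-Hochberg adjusted p = 0.000169), and lay 8.32 ± 0.65 below the housekeeping genes (limma, Benjamini-Hochberg adjusted p = 6.67e-06). Over the members with a mean of at least 10 counts these values were -1.54 and 6.39. The list was not uniformly low. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), a nuclear speckle RNA, gave 128, 335 and 913 TPM in replicates 1, 2 and 3, and Neat1, the scaffold of paraspeckles, 12.9, 24.1 and 66.9 TPM. Both lay above the reference, and the imprinted RNA Airn and the X-linked RNA Firre, named after their values were seen, lay below it at 0.533 and 1.25 TPM, on either adjustment. Neat1 lost its call without replicate 2 (2.10 log2 units, against 2.06) and in the second quantification (1.54). Without replicate 3, Xist lay below the reference (-1.37, against -0.67). Small nuclear and nucleolar RNAs lay 1.81 ± 0.25 log2 units above the reference (limma, Benjamini-Hochberg adjusted p = 0.000131), led by Rn7sk (7SK) at 33002, 77014 and 83514 TPM, with 5 above and 1 below it of 6 tested, on either adjustment. Of the 9 members of this list, 3 were at 0 TPM, and over the members with a mean of at least 10 counts the list median lay 11.44 log2 units above the reference. The cytosolic noncoding RNAs lay 0.35 ± 0.17 log2 units above it (limma, Benjamini-Hochberg adjusted p = 0.0307), with 5 above and 2 below of 9 tested on either adjustment, led by the 7SL genes Rn7s1 and Rn7s2, which are identical to each other, at 309130.0 and 309907 TPM; the vault RNA Vaultrc5 averaged 206 ± 41.7 TPM, but 19.4 TPM in the second quantification, a centred log2 ratio of -2.12. The median of the cytosolic list was -1.46 ± 0.36 log2 units from that of the nuclear small RNAs (limma, Benjamini-Hochberg adjusted p = 0.000738). This difference was -9.61 over the members with a mean of at least 10 counts and did not pass in the second quantification (-0.27). By summed TPM the order was the opposite, with 619330 for the cytosolic and 124480 for the nuclear list. Some RNAs at 0 TPM in the first quantification were measured in the second. Rny3, Rny1, Rnu5g and Snord118, named after their values were seen, averaged 25.2, 5.87, 2.33 and 1.63 TPM there. The level of the cytosolic list against the reference lost its call without replicate 1 (0.26) and without replicate 2 (0.34), and lay at -0.68 against genes with at least 5 TPM.

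Genes of energy metabolism and protein synthesis lay above the reference. The mitochondrially encoded mRNAs lay 5.33 ± 0.82 log2 units above it (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 7.87e-05), with 12 of 13 genes called on either adjustment. The adenosine triphosphate synthase gene mt-Atp8 averaged 2027 ± 1087 TPM, the cytochrome oxidase gene mt-Co1 1111 ± 499 TPM and the complex I gene mt-Nd1 421 ± 212 TPM. This order depended on the quantification, since in the second mt-Atp8 averaged 365 TPM and mt-Co1 427. The remaining gene, mt-Co2, named after its values were seen, gave 7.46, 5.16 and 4.48 TPM. Nuclear-encoded respiratory chain genes lay 1.82 ± 0.06 log2 units above the reference (limma, Benjamini-Hochberg adjusted p = 2.83e-05), with 67 above and 8 below of 87 tested on either adjustment, led by Cox4i1 at 191 ± 34.3 TPM, and 3.51 ± 0.89 below the mitochondrial mRNAs (limma, Benjamini-Hochberg adjusted p = 0.000504). Glycolysis genes lay 2.83 ± 0.09 above the reference (limma, Benjamini-Hochberg adjusted p = 6.67e-06), with 13 of 17 called on either adjustment, and 1.01 ± 0.14 above the respiratory chain genes (limma, Benjamini-Hochberg adjusted p = 0.000464). Gapdh averaged 243 ± 31.9 TPM, the aldolase gene Aldoa 128 ± 15.0 TPM and the pyruvate kinase gene Pkm 93.3 ± 7.74 TPM. Ribosomal protein genes lay 4.86 ± 0.17 above the reference (limma, Benjamini-Hochberg adjusted p = 1.93e-06), with 81 above and 1 below of 83 tested on either adjustment, led by Rpl41 at 789 ± 84.3 TPM. Genes for secretory and lysosomal proteins, whose mRNAs are translated at the endoplasmic reticulum, lay 4.81 ± 0.17 above it (limma, Benjamini-Hochberg adjusted p = 1.93e-06), with 20 of 20 called on either adjustment, led by Psap at 4059 ± 200.5 TPM, Ctsd at 2731 ± 225 TPM and Ctsb at 2131 ± 209 TPM. They differed from the housekeeping genes by -0.04 ± 0.23 log2 units (limma, Benjamini-Hochberg adjusted p = 0.758), and the sign of this difference varied between the libraries. Cell cycle genes lay -2.24 ± 0.42 log2 units from the reference (limma, Benjamini-Hochberg adjusted p = 0.000224), with 16 of 22 genes below it and 2, the proliferation markers Pcna at 59.2 ± 9.48 TPM and Mki67 at 22.6 ± 6.08 TPM, above it on either adjustment. Histone genes expressed in S phase lay -1.15 ± 0.28 from it (limma, Benjamini-Hochberg adjusted p = 0.0009), with 5 above and 33 below of 64 tested on either adjustment. That share below was near the share over all genes tested, 6742 of 13327. Hist2h2aa2 was the highest histone gene at 42.7 ± 3.47 TPM.

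The replicates differed most in mitochondrially encoded, nuclear noncoding and late response RNAs. Each list's median SD of log2 CPM (counts scaled to library size) over the 3 libraries was divided by the median of that of 10000 random lists of equal expression. The ratio was 9.28 for the mitochondrially encoded mRNAs, of which 12 of 13 were highest in replicate 3, and 9.23 for the nuclear-retained long noncoding RNAs, of which 6 of 6 were highest there. It was 6.19 for nuclear small RNAs (Benjamini-Hochberg adjusted p = 0.00153 from the random lists), 4.30 for the late response genes, 3.04 for cytokines and chemokines, 2.85 for cell cycle genes, 2.30 for interferon-stimulated genes and 1.83 for ribosomal protein genes. All of these but the nuclear small RNAs had an adjusted p of 0.000657, the smallest that 10000 permutation draws over 23 lists gave. Members of a list can move together, which the random lists do not copy, so the p-values from these draws may be too small. Replicate 1 was highest for 19 of 22 cell cycle genes, 23 of 26 interferon-stimulated genes and 73 of 82 ribosomal protein genes. It was highest for 38.3% of all 12330 genes tested. The immediate early genes (2.25), intron detention genes (1.97), neutrophil markers (3.04), feedback regulators (1.56) and histone genes (1.32) also varied more, and the respiratory chain genes (0.773) less, than matched lists, with Benjamini-Hochberg adjusted p = 0.00115, 0.0156, 0.0201, 0.0209, 0.0329 and 0.0203 from the permutation draws. The ratios of the other lists tested, among them macrophage markers (0.864), housekeeping (0.899), glycolysis (1.04), TLR4 (0.958), stress (1.22), secretory (1.33), alternative activation (1.26), cytosolic noncoding (1.38) and dendritic cell genes (1.57), did not pass the threshold. On a log2 scale and with 1 replicate left out, the ratio ran from 2.41 to 3.66 for the nuclear-retained RNAs (3.21 with all libraries) and from 1.27 to 2.23 for the cell cycle genes (1.51), past the threshold each time. That of the cytokines lost its call without replicate 1 (0.93), as did that of the late genes (0.05), and that of the feedback regulators without replicate 1 (0.53) or 3 (0.05). The histone genes lost it without replicate 1 (0.07) and turned without replicate 2 (-0.15). Without replicate 3 the calls of the neutrophil (1.18), respiratory chain (-0.18) and intron detention lists (0.16) ended, and the secretory genes passed (0.86).

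**Figure D3:**
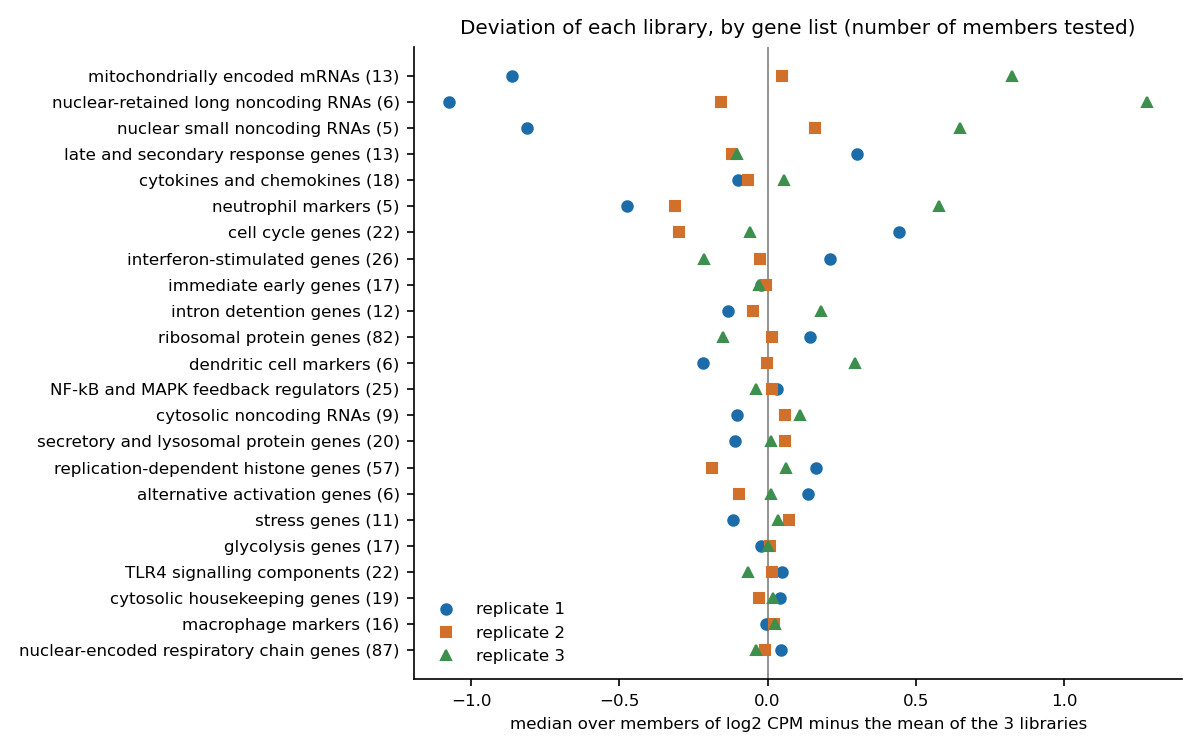
Median over the members of each list of log2 CPM minus the mean of the 3 libraries, with replicates 1, 2 and 3 as points and lists ordered by their variation ratio. The mitochondrially encoded mRNAs lay at -0.86, 0.05 and 0.82 in replicates 1, 2 and 3, and the interferon-stimulated genes at 0.21, -0.02 and -0.21.

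Among single genes, 281 of 12330 varied more than the trended dispersion (edgeR goodness of fit, Benjamini-Hochberg threshold 0.05), 53, 18 and 210 of them highest in replicates 1, 2 and 3. They included 111 protein-coding genes, 71 unclassified transcribed regions, 23 long intergenic noncoding RNAs and 17 small nuclear RNAs. Several small nuclear RNA entries carried identical values, such as Rnu1a1 and Gm22068 at 270, 297 and 655 TPM, named after their values were seen. These counts, and the 210 highest in replicate 3, therefore do not all stand for separate measurements. The count was 162, 180 and 96 without replicates 1, 2 and 3. The mitochondrial leucyl-transfer RNA synthetase gene Lars2 gave 31.8, 1.42 and 1.58 TPM, and the ribosomal RNA gene CT010467.1 2118, 22.6 and 66.0 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 gave 30.9, 1.44 and 4.67 TPM and 33.5, 3.89 and 10.7 TPM. Gm49369, a gene that overlaps Ctsd on the same strand and matches it over 671 of 833 bases, gave 85.1, 849.7 and 876 TPM, and Gm20721, which overlaps Gnas on the opposite strand with 99.3% identity, 1.52, 15.2 and 14.3 TPM. The small nuclear RNA copies Gm23444 and Gm23472 shared the values 199, 194 and 895 TPM, and the noncoding RNA Gm26917, next to CT010467.1, gave 41.5, 58.5 and 225 TPM. The calls of some of these genes depended on single libraries. CT010467.1 lost its call above the reference without replicate 3 (5.01 log2 units, against 4.47), while without replicate 1 Lars2 lay below it (-1.97, against -0.61) and Gm20721 above it (1.25, against 0.10).

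Transcripts annotated with a retained intron, a form often held in the nucleus, took a small share of most genes. The median share was 1.81% ± 1.14 over 5543 genes with both kinds of transcript (SD, n = 3) and 0.439% ± 0.155 over 14 housekeeping genes. It was 7.15% ± 4.68 for 12 genes known for intron detention, such as the splicing kinase genes Clk1 and Clk4, 6.31% ± 3.98 for 17 interferon-stimulated genes, 2.41% ± 1.25 for 16 feedback regulators and 0.651% ± 0.504 for 9 cytokines and chemokines. The differences from the housekeeping genes were 6.71, 5.87, 1.97 and 0.212 percentage points. None passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0748, 0.0748, 0.0748 and 0.671 over 4 differences). Without replicate 3 the intron detention and interferon-stimulated differences, then 4.19 and 3.71 points, passed. In the second quantification those of the intron detention genes, feedback regulators and interferon-stimulated genes passed, at 8.08, 3.50 and 8.18 points. As genes, the intron detention list lay 1.02 ± 0.07 log2 units above the reference (limma, Benjamini-Hochberg adjusted p = 0.000267), with 6 of 12 called on either adjustment, led by Srsf5 at 80.6 ± 9.54 TPM, and at -0.01 against genes with at least 5 TPM. Clk1 was called at 13.4 ± 1.23 TPM and lost its call without replicate 3 (0.98 log2 units, against 1.02) and in the second quantification (0.50); Srsf7 passed without replicate 1 (1.05, against 0.98).

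**Figure D4:**
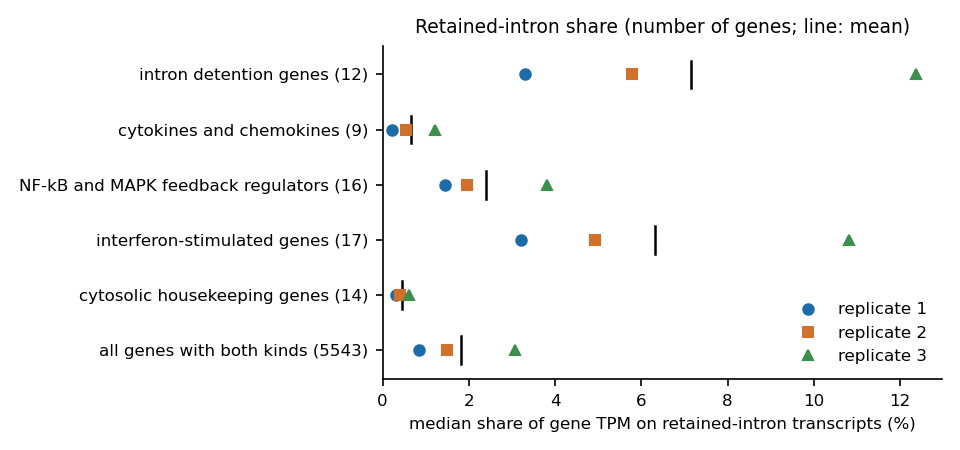
Median share of a gene's TPM on retained-intron transcripts (%) per list in replicates 1, 2 and 3, with the mean as a line and the number of genes in brackets. For the intron detention genes the shares were 3.31%, 5.79% and 12.4% in replicates 1, 2 and 3, and for the housekeeping genes 0.299%, 0.413% and 0.606%.

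Of the genes chosen for a look at isoforms, 5 were measured almost wholly as a single transcript. Tnf-201 took 100.0% of Tnf TPM, Nfkbia-201 99.6%, Il1b-201 99.4%, Myd88-201 99.0% and Ptgs2-201 the whole of its gene. Il1rn was split, with Il1rn-201 at 79.9% ± 1.18 and Il1rn-204 at 13.2% ± 0.852 (SD, n = 3), as was Nfkbiz, an atypical NF-kB regulator, with Nfkbiz-204 at 79.9% ± 3.45 and Nfkbiz-203 at 18.8% ± 3.20. Pkm-201 took 86.9% ± 1.01 of Pkm. Among splicing regulators the main transcript took 82.0% ± 8.36 for Clk1-201, 79.6% ± 3.56 for Srsf3-202, 65.1% ± 2.09 for Srsf7-208, 63.5% ± 3.46 for Tra2b-204 and 44.8% ± 3.68 for Clk4-201. Srsf3-201, annotated as a target of nonsense-mediated decay, held 12.3% ± 2.96 of Srsf3. In the second quantification the same transcript led for each of these genes, with Tra2b-204 at 42.0% ± 1.11.

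The 2 deposited quantifications gave like values for most protein-coding genes and differed mostly in short and noncoding genes. After centring on the median log2 ratio of -1.25, 258 of 9481 genes were higher in the second quantification and 183 in the first (limma, Benjamini-Hochberg threshold 0.05, log2 ratio of at least 1). These were 0.788% of protein-coding genes, against 87.8% of small nuclear RNAs, 82.4% of microRNA genes and 62.3% of processed pseudogenes. Among genes with a transcript length at hand, 172 and 102 of 591 genes under 500 bases were higher in the second and the first, against 86 and 76 of 8885 longer genes. A few genes without one were left out of this split. Without replicate 2 the counts were 167 and 110. Among genes with a mean of at least 10 TPM in the first quantification, the largest log2 ratios were 5.12 ± 0.15, 4.53 ± 0.16 and 3.64 ± 0.28 for Gm26809 and the ribosomal protein copies Rpl10-ps3 and Gm10275 (of Rpl10 and Rpl12), and -10.38 ± 0.57, -8.67 ± 0.44 and -8.47 ± 0.29 for Gm10222, Gm10443 and Gm10076, near-identical to mt-Nd4l, Rps28 and Rpl41. Gm10076 accordingly lay above the reference in the first quantification (5.61 log2 units) and below it in the second (-3.32). The second quantification held 0 TPM for Gm10222 and Gm10443 and 0.288 TPM for Gm10076. The size of these negative ratios therefore depends on the pseudocount of 0.1 TPM. A search made after the values were seen found a copy with at least 95% identity over at least 80% of the transcript for 20 of 135 named genes, among them Gapdh, Lyz2 and Rpl41, for which the quantifications gave like values all the same (log2 ratios -0.13, -0.16 and -0.01). Genes with and without copies were not compared in a test. For mt-Co2, the annotated pseudogene Gm28661 (chromosome 1, 24614885 to 24615565, mm10) matched 681 of 684 bases at 100% and held 696, 894 and 1565 TPM in replicates 1, 2 and 3, where mt-Co2 held 7.46, 5.16 and 4.48.

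**Figure D5:**
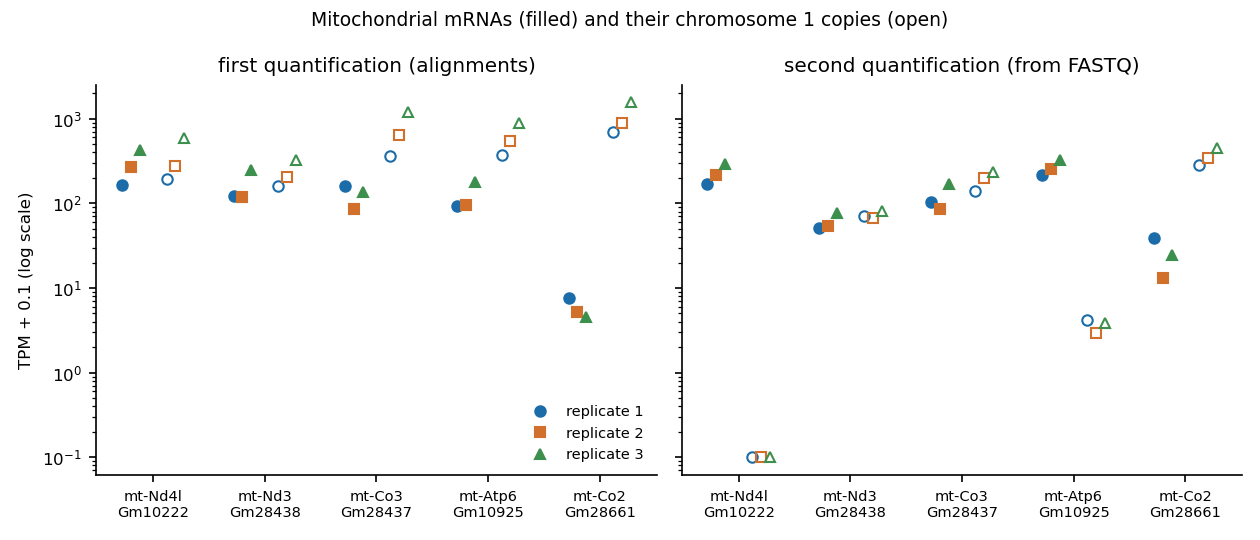
TPM + 0.1 (log scale) of 5 mitochondrially encoded mRNAs (filled) and of their annotated copies on chromosome 1 (open) in replicates 1, 2 and 3, by quantification. Gm28661 exceeded mt-Co2 in both, at 696 against 7.46 TPM in replicate 1 of the first and 286 against 39.1 of the second, whereas Gm10222 held 194 TPM in replicate 1 of the first and 0 in the second.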

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

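Of the tests in this part, the comparison of interferon-stimulated with housekeeping genes and the search for copies of the named genes were chosen only after the result was seen, and the patterns themselves were found in the same data. Reads of the sequencing control phage phiX174, which the comparisons did not use, numbered 149923, 78564 and 58293 expected counts in replicates 1, 2 and 3 (0.443%, 0.164% and 0.0982% of the total), above the 3 counts that a count of 0 allows. The numbered entries outside the gene annotation held 4 expected counts in replicate 2 and 4 in replicate 3, just above that limit, and 0 in replicate 1. Replicate 1 had the fewest counts, so its 0 allows about as many at the depth of the others. No difference between the libraries is shown by these entries. The libraries form 1 group, so no biological explanation was tested for any of the patterns below.

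Nuclear-retained long noncoding RNAs were higher in replicate 3 than in replicate 1 by a median of 2.40 log2 units over 6 detected members, with Malat1 at 3.10. Transcript length bias is argued against, because protein-coding genes of matched length showed a median of 0.00744 of the members' log2 ratio (-0.0238 to 0.0652 over 5 members with enough matched genes). Carry-over of nuclear RNA in differing amounts may contribute, as 199 long intergenic noncoding RNA genes as a class were higher in replicate 3 relative to protein-coding genes by 0.144 log2 units (95% bootstrap interval 0.0147 to 0.211). The interval is over genes and does not measure the spread between libraries. That shift of the class is far smaller than the shift of the list, but nuclear small RNAs (1.46) and the median retained-intron share of all genes (3.07% against 0.852%) were higher in replicate 3 than in replicate 1 too, as were the neutrophil markers (1.05, 5 of 5 highest in replicate 3) and the mitochondrially encoded mRNAs (1.68), which are not nuclear. No nuclear fraction was used here to compare with, and differences between the cultures stay open and untested.

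Interferon-stimulated genes were higher in replicate 1 than in the mean of the other two by a median of 0.315 log2 units, 25 of 26 genes being above 0. Length and GC bias between the libraries are argued against as the whole cause, because random lists matched on expression, length and GC content lay between -0.0417 and 0.101. To look at a single scaling factor common to all mRNAs, the list was set against the housekeeping genes, whose median it exceeded by 0.253 (95% bootstrap interval 0.126 to 0.549). The interval resamples genes and not libraries, so it does not measure the spread between libraries. The list was also picked for its shift in these scaled counts, which made such an excess likely, so no conclusion is drawn. Late response (0.45), cell cycle (0.66), histone (0.24, 43 of 57 above 0) and ribosomal protein genes (0.21) moved in the same direction, whereas cytokines and chemokines (-0.15, 7 of 18 above 0) and immediate early genes (-0.03) did not. Neutrophil markers (-0.71), mitochondrially encoded mRNAs (-1.29) and nuclear-retained RNAs (-1.61) were lower in replicate 1, and its ribosomal RNA share was the highest, at 0.218% of the TPM. A difference between the cultures may remain as a hypothesis, which these libraries cannot test.

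The mt-Co2 mRNA averaged 5.70 ± 1.56 TPM, where the other mitochondrially encoded mRNAs averaged 123 to 2027 TPM. Its annotated near-identical nuclear copies held 93.3 times its TPM in the library where the ratio was lowest, and 349 times where it was highest. The bound written before the ratio was computed was 10 times in every library, which the second quantification, with a lowest ratio of 7.32, did not reach. Reads shared with these copies are therefore a candidate explanation for the low value of mt-Co2 in the first quantification. Chromosome 1 copies of mt-Atp6, mt-Co3, mt-Nd3 and mt-Nd4l also exceeded these genes in every library of the first quantification. In replicate 1 they held 377 against 93.4, 366 against 158, 161.3 against 120.5 and 194 against 163 TPM. The lowest of the other mRNAs, mt-Atp6 at 123 TPM, averaged 266 TPM in the second quantification, where TPM ran lower for most genes. Its centred log2 ratio was 2.41, so values in this range may be lowered too. Whether the reads come from the mitochondrial genome or from chromosome 1 was not tested.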

How the results depend on the processing

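None of the tests in this part was chosen after the result was seen. List levels kept their direction and their side of the threshold in 302 of 327 alternatives run, contrasts in 167 of 170, named genes in 824 of 877, list variation in 108 of 138 and retained-intron shares in 16 of 24. Of the named genes, 13 values lost a call, 22 gained one and 18 changed sign. The losses were Clk1, Isg20 and Ngp with a pseudocount of 1, Cd4, Clk1, Neat1, S100a9 and Srsf3 in the second quantification, and Ngp, Neat1, CT010467.1 and Clk1 without 1 replicate. No paired analysis was possible because the samples form 1 group. Depth limits genes near 0.1 TPM, and 3 libraries limit the spread. Except where stated, the cause was not tested.

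Log2 values against the reference, or between lists, changed as follows. With list means the late genes lay at -0.43 (median -0.12), the stress genes at 0.33 (-0.79) and the secretory minus housekeeping contrast at 0.00667 (-0.04). In the second quantification the late genes lay at -0.61, the TLR4 components at 0.26 and the contrast of cytosolic with nuclear small RNAs at -0.27. Restricting the lists to members with a mean of at least 10 counts moved the nuclear small RNAs to 11.44 (1.81) and their contrast with the cytosolic noncoding RNAs to -9.61 (-1.46), since its lowest members were left out by construction. With FPKM the late genes lay at 0.10. Against genes of at least 5 TPM, the late genes lay at -1.14, TLR4 components at -0.27, cytosolic noncoding RNAs at -0.68 and intron detention genes at -0.0109, since that reference is higher by construction. Against the housekeeping genes, a higher reference still, the immediate early genes lay at -2.61, feedback regulators -1.80, interferon-stimulated genes -2.04, late genes -4.96, TLR4 components -4.09, nuclear small RNAs -3.04, cytosolic noncoding RNAs -4.50, respiratory chain -3.03, glycolysis -2.02, secretory -0.0409 and intron detention genes -3.83, and the macrophage markers (0.30), mitochondrial mRNAs (0.48) and ribosomal protein genes (0.0163) no longer passed. Leaving out 1 replicate moved the secretory minus housekeeping contrast over -0.11 to 0.0940 and the cytosolic noncoding RNAs over 0.26 to 0.43.

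Single genes changed sign in the second quantification for Cxcl3 (-0.43), Egr3 (-0.0880), Gm10076 (-3.32), Gm20721 (-3.77), Klf2 (-0.0525), Lars2 (1.19), Usp18 (-0.12), Vwf (-0.53) and mt-Rnr2 (0.91), and with a pseudocount of 1 for mt-Rnr2 (0.0147). Leaving out 1 replicate moved Gm20721 over -0.51 to 1.25, Lars2 over -1.97 to 0.0910, mt-Rnr2 over -1.20 to 0.82, Cxcl3 over -0.13 to 0.30 and Il6 over -0.26 to 0.0906. With no filter on low values 14489 genes lay below the reference (6742), since more were tested, and with no minimum difference 4094 lay above it (2726). The number of genes more variable than the trend (281) ran from 96 without replicate 3 to 180 without replicate 2. Of the 281, 210 were highest in replicate 3. Fewer libraries give less power, but the cause of the differing counts was not tested. With 1 replicate left out, the genes higher in the second (258) and first quantification (183) ran from 167 to 274 and 110 to 171. These numbered 1061 and 7160 with no filter on low values, and those higher in the first 107 with a pseudocount of 1.

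The log2 ratio of list variation, with no filter on low counts, was 0.50 for feedback regulators, 1.27 for neutrophil markers, -0.20 for respiratory chain, 0.34 for histone and 0.74 for intron detention genes, which no longer passed, and changed sign for TLR4 (0.14) and glycolysis genes (-0.13). With tagwise dispersion it was 0.15 for feedback regulators and -0.0457 for respiratory chain genes, which no longer passed, 0.18 for secretory genes, which passed, and 0.00371, 0.12, -0.0236 and 0.0421 for TLR4, macrophage, glycolysis and housekeeping genes, which changed sign. Leaving out 1 replicate gave 0.0538 to 0.92 for feedback regulators, -0.17 to 0.24 for TLR4, 0.93 to 1.79 for cytokines, -0.17 to 0.42 for housekeeping, -1.30 to 0.77 for cytosolic noncoding, 0.16 to 1.37 for intron detention, 0.0505 to 2.36 for late, 1.18 to 2.19 for neutrophil, -0.74 to -0.18 for respiratory chain, -0.15 to 0.90 for histone, 0.0521 to 0.86 for secretory and -0.24 to 0.48 for stress genes. The ratios of the interferon-stimulated genes, mitochondrial mRNAs and nuclear-retained RNAs kept their calls in all alternatives run. Retained-intron differences from the housekeeping genes passed in the second quantification for intron detention genes (8.08 points), feedback regulators (3.50) and interferon-stimulated genes (8.18), and with list means for feedback regulators (3.77) and interferon-stimulated genes (7.07), where that of the cytokines passed in the opposite direction (-1.74). Single genes pull these means. Psma3 held 27.0% and the next housekeeping gene, Eif4a1, 2.05%, while Tnip3 held 62.1% and the next feedback regulator, Nfkb1, 7.96%. These genes were named after their values were seen. The list-mean results of the cytokines and feedback regulators thus rest largely on single genes, and the means were not recomputed without them. Leaving out 1 replicate gave 3.71 to 7.36 points for interferon-stimulated and 4.19 to 8.57 for intron detention genes.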

Other observations

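No test in this part was chosen after the result was seen. The 10 most abundant nuclear-encoded mRNAs averaged 1793 to 6555 TPM. The ferritin chains Fth1 and Ftl1, which store iron, averaged 6555 ± 663 TPM and 6241 ± 301 TPM (SD, n = 3), ahead of the lysozyme gene Lyz2 at 4347 ± 1009 TPM and Psap, the precursor of the saposins that activate lysosomal lipid hydrolases, at 4059 ± 200.5 TPM. The lysosomal proteases cathepsin D (Ctsd) and cathepsin B (Ctsb) averaged 2731 ± 225 TPM and 2131 ± 209 TPM. Selenop, encoding a secreted selenium carrier, and Gpnmb, a transmembrane glycoprotein of lysosome-rich macrophages, averaged 2254 ± 546 TPM and 2133 ± 88.0 TPM. The actin-binding peptide gene Tmsb4x and Actb completed the 10 most abundant, at 1889 and 1793 TPM.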
